A study of Mus musculus with 12 samples.

How the data were processed

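Gene expression was taken from 12 arrays of the mouse Affymetrix 430 2.0 type, 3 for each of 4 groups: leukaemia cells with wild-type or deleted MBD2, and CD4+CD8+ thymocytes with wild-type or deleted MBD2. Per the labels, the leukaemias were driven by Notch1 and taken as GFP+ bone marrow cells once more than 50% of white blood cells were GFP+, and 7 µg of total RNA per sample was labelled as biotin cRNA. The deposited values are probe set intensities on a linear scale, from 3.07 to 21620, already summarized by the authors; the methods of summarization, background correction and normalization are not given in the sources used here. Array medians on the log2 scale lay between 5.71 and 5.79, a spread of 0.0752 that is below the limit of 0.1 set for normalizing again, so no further normalization was applied. Values were taken as log2(value + 16).

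The array annotation gave 1 gene to 34945 of 45101 probe sets, several genes to 932 and none to 9160, with 64 control probe sets. Symbols were compared by gene identifier with a GRCm38.p6 gene table, which matched 34741 single-gene probe sets and renamed 0; this table served only for names and for the order of genes near Mbd2, and no coordinates are given. Each of 18193 genes was represented by its single-gene probe set with the highest mean over the 12 arrays. Genes above the 25th percentile of their array on at least 3 arrays were tested, 15420 in all, and 2773 were left out. No detection calls were used; the highest control probe set without a target gave an intensity of 35.3, and lower levels cannot be told from background.

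Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust), each comparison of 2 groups in its own fit, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. The difference between the genotype effects of the cell types was tested in a fit of all 12 arrays. Log2 differences are limma coefficients with their standard errors (SE), intensities are group means with standard deviations, and adjusted p is limma's unless a list is named. The 39 gene lists hold 1148 entries, of which 1065 matched a probe set and 1001 were tested; 38 lists had at least 5 tested members and were tested with camera at a preset correlation of 0.01, with a second p from a correlation estimated per list. List members were counted over all genes and again adjusted over the list alone. With 3 arrays against 3 the smallest exact p of a rank test is 0.1. Plots were made with matplotlib 3.10.9 in Python 3.11.15.

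The lists, the comparisons and their tests, the rule for naming genes, and the alternatives and tests not described as later ones were chosen before the data were examined. By this rule the text names Mbd2, the up to 10 higher and 10 lower genes with the largest differences per comparison whose groups do not overlap (clone names left out, filled to 5 by smallest p where fewer pass), up to 4 passing members of each list described with the smallest p, or the 2 with the smallest p where fewer pass, and up to 5 genes per direction for the difference of effects. Sex-linked genes, Notch1, Myc, Cd4 and Cd8a may be named in any comparison. For thymocytes, members are named only from lists that passed and from the monocyte and macrophage list, a choice made after the results were seen. T-cell-receptor segments, Csf1r in both cell types and Lyz1 in thymocytes, outside this rule, were also chosen after their values were seen.

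The labels give separate samples with a replicate number but no sex, age, litter or array date, and do not say whether equal numbers mark a shared origin, so the p-values measure only the spread between these samples. To check for pairing, samples were correlated across genes after group means were taken off. Between leukaemia genotypes equal numbers gave r of 0.40, 0.24 and 0.55, and between wild-type leukaemias and thymocytes 0.45, 0.44 and 0.58. The sample with the same number was the best match in each case. In the first of these comparisons, numbers 1 and 3 also share the set defined by the poly-A controls, while number 2 joins an array with signal and another without it. In the second all numbers share the set. Arrays of a group correlated at 0.976 to 0.993.

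Alternatives were quantile normalization, centring on the 75th percentile, no filter or a filter at the array median, the mean of the probe sets of a gene, eBayes with trend and robust, array weights, the replicate number as a block, leaving out each array in turn, added constants of 1 and 64, and all 12 arrays in each fit. After the data were seen, the poly-A set as a block, only arrays with or without poly-A signal, the log2 Gapdh 3' to 5' ratio as a covariate, leaving out genes of the X and Y chromosomes, and leaving Xist out of the list of genes linked to MBD2 were added. The poly-A set comes from 24 control probe sets for transcripts added to the RNA before labelling.

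A self-test added known differences to simulated arrays, 200 changed genes in 10 repeats. Values were drawn from normal distributions with the moderated variance that limma gave each gene. Differences of log2 1 were called for 82.6% of genes in the leukaemia genotype comparison and 88.7%, 86.7% and 87.3% in the others, and differences of log2 2 for at least 99.4%. False calls numbered 10.2 to 11.5 per repeat, and a list shifted by 0.5 was found in 10 of 10 repeats. The simulated genes varied independently of each other and without the poly-A set. Their variances were moderated ones and not those observed, so recovery in the data may differ. The self-test therefore does not show how reliable list calls are when the members of a list are correlated. With 3 arrays per group, differences of 2-fold or less are missed for some genes, and a group without calls is no proof of equal expression.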

Results

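Deletion of MBD2 lowered the Mbd2 transcript in leukaemia cells from an intensity of 820 ± 119 to 54.4 ± 12.4 (mean ± SD, 3 arrays per group), a log2 difference of −3.58 (SE 0.17, adjusted p = 3.16e-05). A second Mbd2 probe set fell from 371 ± 262 to 12.1 ± 4.46 (log2 −3.47, SE 0.59, adjusted p = 0.00851). The largest gain in the knockout leukaemias was Cpa3, which encodes a mast cell carboxypeptidase and went from 20.7 ± 3.16 to 7622 ± 622 (log2 7.70, SE 0.11, adjusted p = 5.15e-07). Notch1, which the labels name as the driver of these leukaemias, rose from 1457 ± 140 to 5664 ± 1279 (log2 1.92, SE 0.19, adjusted p = 0.000744). The data do not show whether its probe set reads the form that drives the leukaemias. The genes of both chains of the CD8 co-receptor fell, Cd8a from 2729 ± 527 to 218 ± 147 (log2 −3.70, SE 0.40, adjusted p = 0.00113) and Cd8b1 from 3632 ± 1107 to 62.3 ± 33.2 (log2 −5.57, SE 0.34, adjusted p = 9.88e-05). Cd4 fell from 271 ± 25.3 to 92.7 ± 1.24 (log2 −1.39, SE 0.10, adjusted p = 0.000199), whereas Myc did not pass (701 ± 325 and 589 ± 326, log2 −0.28, SE 0.54, adjusted p = 0.797).

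**Figure D1:**
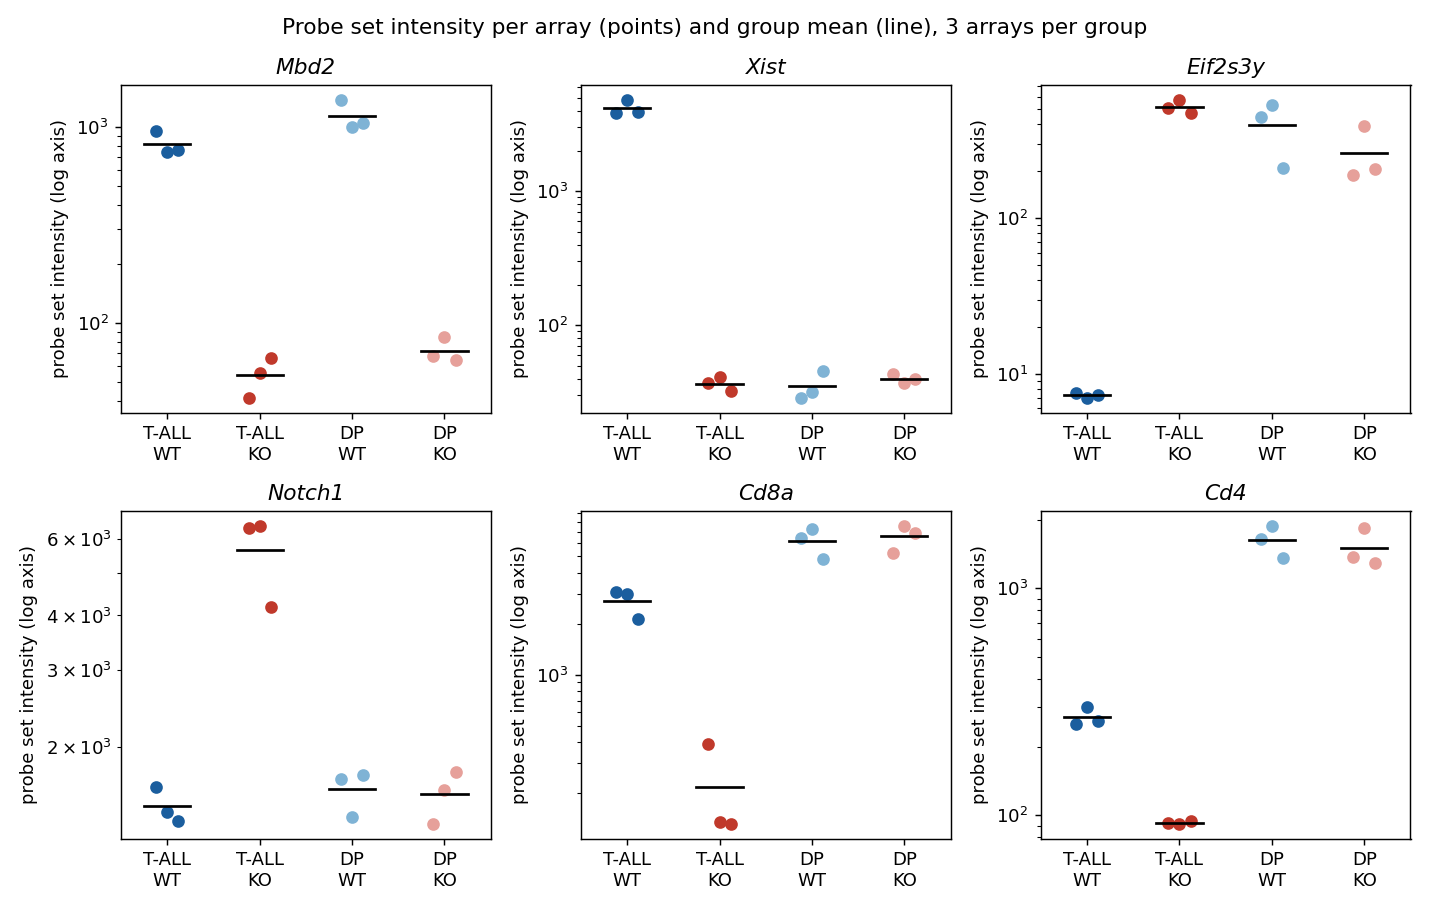
Intensity of the probe set used for Mbd2, Xist, Eif2s3y, Notch1, Cd8a and Cd4 on each array (points, log axis), with the mean of each group of 3 arrays as a line.

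Of the 15420 genes tested, 1417 were higher and 1076 lower in knockout than in wild-type leukaemias at an adjusted p under 0.05, and 802 and 387 of these changed at least 2-fold. The 3 knockout arrays lay outside the range of the 3 wild-type arrays for 5151 genes, 33.4% of those tested, where chance gives 10%. Higher genes made up 56.8% of the calls, and 45.0% when arrays were centred on their 75th percentile. With the replicate number as a block the lower calls numbered 1936. Leaving out wild-type replicate 2 brought the calls to 877 higher and 535 lower, and leaving out wild-type replicate 1 brought the lower calls to 607.

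Among the 10 genes with the largest gains were the complement-receptor-like Cd93 (18.8 ± 1.43 to 3454 ± 157, log2 6.64), the growth factor receptor gene Pdgfrb (28.8 ± 10 to 4215 ± 652, log2 6.57) and Tgfb2 (13 ± 1.61 to 2029 ± 223, log2 6.13). The progenitor homeobox gene Hhex rose by log2 6.03, the cytotoxic granule protease gene Gzmb by 5.88, the TIE2 ligand gene Angpt1 by 5.54, Ifitm2 by 5.54, the thrombin receptor gene F2r by 5.35 and the LIM-domain gene Lmcd1 by 5.34. Wild-type leukaemias gave mean intensities for Cpa3, Cd93, Pdgfrb, Tgfb2, Hhex, Gzmb, Angpt1, Ifitm2 and Lmcd1 no higher than the highest control probe set without a target (35.3), which single arrays exceeded for Pdgfrb (38.7) and Lmcd1 (39.3), so the size of these differences depends on the constant added before the logarithm. Besides Cd8b1, the largest losses were Xist (log2 −6.32), the actin regulator Cttn (1271 ± 402 to 15.1 ± 0.178, log2 −5.33), the pre-T-cell-receptor gene Ptcra (1583 ± 183 to 31.6 ± 7.99, log2 −5.08), the thymus-homing receptor gene Ccr9 (2066 ± 543 to 114 ± 45.1, log2 −4.04), Nrp1 (log2 −3.96) and the lysosomal protease gene Ctsl (log2 −3.88). The transporter genes Slc36a4 and Slc30a4 fell by log2 3.85 and 3.78, and the desmosome gene Dsp by 3.71.

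**Figure D2:**
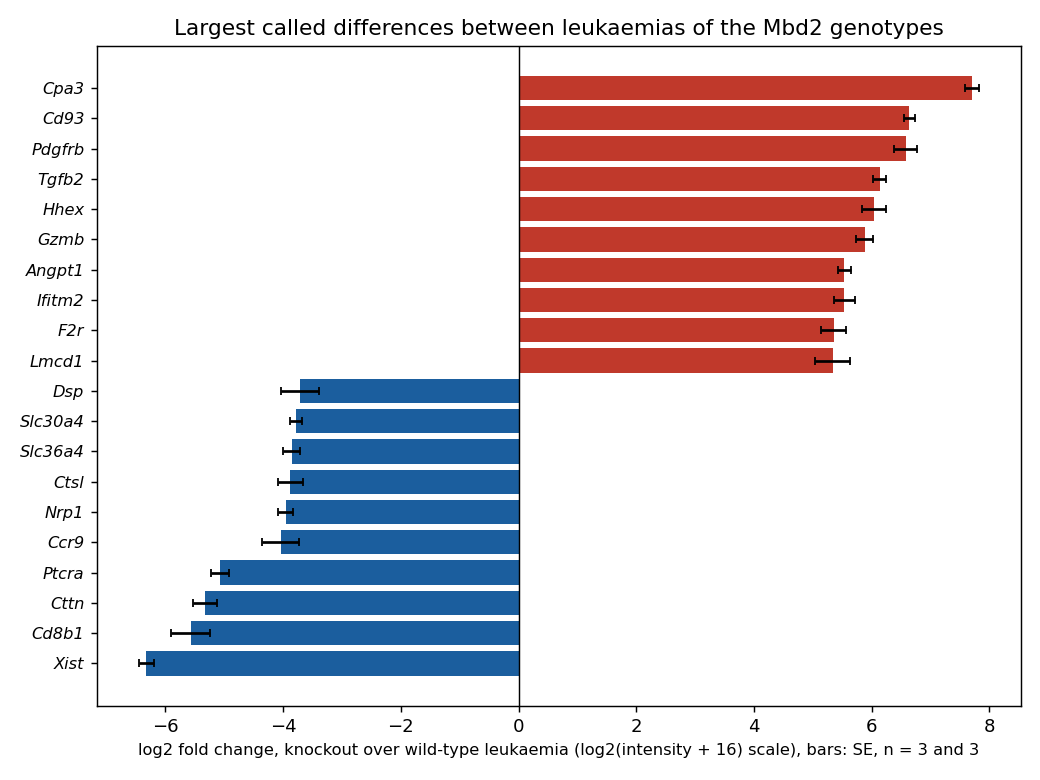
Log2 fold change of knockout over wild-type leukaemias (n = 3 and 3) for the 10 genes with the largest gains and the 10 with the largest losses, with standard errors.

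Genes of CD4+CD8+ thymocyte identity were lower as a list in the knockout leukaemias (adjusted p = 0.00838, and 0.262 with an estimated correlation). Of its members 3 were higher, 12 lower and 11 not passing, and 3 and 13 passed when adjusted over the list alone. Besides the co-receptor genes and Ccr9, Ly6d (log2 −3.05, adjusted p = 0.000133) and the chromatin organizer Satb1 (log2 −1.35, adjusted p = 0.00219) were among those that fell. The T-cell-receptor signalling list was higher (adjusted p = 0.00386, and 0.332 with an estimated correlation), with 8 members higher, 1 lower and 20 not passing (10 and 2 over the list alone). Its members Trat1 (log2 2.06), Ptpn22 (log2 1.31) and Tespa1 (log2 1.27) rose. The adhesion receptor gene Cd2 fell from 2156 ± 882 to 149 ± 46 (log2 −3.66, adjusted p = 0.000923).

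Genes of effector and cytotoxic T cells were higher in the knockout leukaemias (adjusted p = 6.03e-06, and 0.262 with an estimated correlation). They counted 11 higher, 1 lower and 16 not passing, and 11 and 1 over the list alone. Gzmb, the granule membrane gene Nkg7 (log2 5.18), Il18r1 (log2 4.57) and Ctsw (log2 2.40) led this list. Genes of natural killer and innate lymphoid cells, of which Gzma (log2 2.10) and Il2rb (log2 0.88) are in both lists, counted 3 higher, 0 lower and 9 not passing, the third being Cd244a (log2 0.95). Their list did not pass (adjusted p = 0.186, and 0.332 with an estimated correlation). Notch targets and components were higher too (adjusted p = 0.0372, and 0.454 with an estimated correlation), at 8 higher, 1 lower and 11 not passing (9 and 2 over the list alone). Hey1 rose from 38.7 ± 7.49 to 683 ± 288 (log2 3.58, adjusted p = 0.00063) and Adgrg1 by log2 2.33, while at the threshold over all genes Ptcra was the single member that fell.

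Transcription factors of the T lineage shifted higher as a list (adjusted p = 0.0496, and 0.262 with an estimated correlation), but were at 0.0553 with the replicate number as a block. Their counts were 7 higher, 3 lower and 12 not passing, and 8 and 4 over the list alone. Gata3 (log2 1.20) and Tox (log2 1.00) rose, and Id3 (log2 −2.16) and Ikzf3 (log2 −1.63) fell. Mature T cell genes divided into 7 higher, 5 lower and 10 not passing, or 10 and 5 over the list alone (list adjusted p = 0.0435, and 0.332 with an estimated correlation). Igfbp4 rose from 412 ± 38.9 to 2949 ± 401 (log2 2.79), while Ms4a6b (log2 −2.65) and Ms4a4b (log2 −2.79) fell. Homing and adhesion genes gave 6 higher, 4 lower and 17 not passing, or 10 and 4 over the list alone (list adjusted p = 0.0435, and 0.262 with an estimated correlation). Selplg (log2 1.34) and Itgb3 (log2 2.25) were among those that rose and Cd44 (log2 −2.98) among those that fell.

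Interferon-stimulated genes were higher in the knockout leukaemias, 19 members against 0 lower and 22 not passing (24 and 1 over the list alone). The list had an adjusted p of 1.71e-09, and 0.332 with an estimated correlation. Usp18, a brake on type I interferon signalling, rose from 22.7 ± 4.14 to 304 ± 41 (log2 3.05, adjusted p = 2.72e-05), and Rtp4 (log2 2.68), Oasl2 (log2 2.39) and the signalling factor Irf9 (log2 1.45) rose with it. The NF-κB target list was higher (adjusted p = 0.00838, and 0.332 with an estimated correlation), through Tnfaip3 (log2 1.35), Tnfrsf9 (log2 1.08) and Ltb (log2 1.40). Besides these 3 it had 1 lower and 19 not passing members (5 and 1 over the list alone).

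Targets of p53 were higher in the knockout leukaemias (adjusted p = 0.00198, and 0.262 with an estimated correlation), with 7 members higher, 1 lower and 20 not passing (7 and 1 over the list alone). The BH3-only gene Pmaip1 rose from 48.6 ± 11.9 to 312 ± 82.3 (log2 2.33), and Plk2 (log2 1.14) and Ercc5 (log2 1.13) rose, while Dcxr fell by log2 1.04. The PI3K and FOXO list was higher (adjusted p = 0.0372, and 0.262 with an estimated correlation), with 6 higher, 2 lower and 18 not passing (8 and 2 over the list alone). Foxo3 (log2 1.71), Txnip (log2 1.36) and Ccng2 (log2 1.14) rose and Irs2 (log2 −1.05) fell.

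Cholesterol synthesis genes were lower in the knockout leukaemias, 11 members against 0 higher and 9 not passing (0 and 16 over the list alone). The list had an adjusted p of 1.78e-06, and 0.262 with an estimated correlation. Idi1 fell from 677 ± 48.5 to 230 ± 78.1 (log2 −1.55), the rate-limiting monooxygenase gene Sqle by log2 1.24, Pmvk by 1.12 and Mvk by 0.84. S-phase genes were lower (adjusted p = 2.25e-07, and 0.262 with an estimated correlation), with 0 higher, 13 lower and 35 not passing (0 and 20 over the list alone). Among them the DNA polymerase delta subunit gene Pold2 fell from 1365 ± 154 to 670 ± 95 (log2 −1.01, adjusted p = 0.00389). Genes of ribosome biogenesis that MYC drives were lower (adjusted p = 1.78e-06, and 0.262 with an estimated correlation). They counted 0 higher, 7 lower and 33 not passing, and 0 and 19 over the list alone, with the spermidine synthase gene Srm at log2 −1.28 and Ppan at log2 −0.93.

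Oxidative phosphorylation genes were lower as a list (adjusted p = 1.84e-06, and 0.332 with an estimated correlation), at 0 higher, 3 lower and 38 not passing (0 and 2 over the list alone). Mitosis genes were lower (adjusted p = 0.00589, and 0.452 with an estimated correlation), at 0 higher, 3 lower and 43 not passing (0 and 3 over the list alone). Sdhb (log2 −1.03) and Ndufa9 (log2 −0.84) of the respiratory chain were called with all 6 arrays and lost the call without wild-type replicate 1. The same held for Cdca3 (log2 −0.94), Bub1b (log2 −0.86) and Birc5 (log2 −0.84) of mitosis.

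Megakaryocyte and platelet genes were higher (adjusted p = 0.00236, and 0.262 with an estimated correlation), with 4 higher, 0 lower and 6 not passing (4 and 0 over the list alone). The transcription factor gene Nfe2 went from 26.4 ± 5.39 to 1296 ± 26.3 (log2 4.96), with F2r, Itgb3 and the platelet integrin gene Itga2b (log2 1.30). Erythroid genes were lower as a list (adjusted p = 0.00719, and 0.332 with an estimated correlation), with 1 higher, 8 lower and 12 not passing (2 and 11 over the list alone). Car2 (log2 −1.76) and Epor (log2 −0.67) fell and Hemgn (log2 2.53) rose. Neutrophil genes were lower as a list (adjusted p = 0.0222, and 0.332 with an estimated correlation), with 0 higher, 2 lower and 15 not passing (0 and 5 over the list alone). Without wild-type replicate 3 their adjusted p was 0.0619. Genes of early progenitors gave 8 higher, 3 lower and 18 not passing. Their median log2 difference was −0.09, but the test pointed higher and did not pass (adjusted p = 0.113, and 0.332 with an estimated correlation). The factors Lyl1 (59.8 ± 9.37 to 2649 ± 327, log2 5.14) and Lmo2 (57.3 ± 6.67 to 1051 ± 202, log2 3.85) rose with Hhex and Nfe2.

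Other fixed lists did not pass between the leukaemia genotypes, although single members did. Wnt targets gave 6 higher, 4 lower and 21 not passing (adjusted p = 0.342). Among them Ccnd2, a D-type cyclin gene, rose from 75.5 ± 3.89 to 1804 ± 263 (log2 4.30), Enc1 rose by log2 2.36 and the secreted Wnt inhibitor gene Wif1 fell from 154 ± 71.4 to 14.4 ± 4.85 (log2 −2.40). Wnt pathway components (0 higher, 2 lower, 43 not passing) and Wnt antagonists (3, 3 and 31) each had an adjusted p of 0.646, as did a list of genes linked to MBD2 in earlier work (3, 2 and 5). DNA methylation and NuRD genes gave 4 higher, 2 lower and 19 not passing (adjusted p = 0.446). Of these, Dnmt3b (430 ± 22.8 to 1622 ± 228, log2 1.87), Tet2 (log2 1.75) and the NuRD subunit gene Mta3 (log2 2.51) rose. Germline genes silenced by methylation gave 0 higher, 3 lower and 19 not passing (adjusted p = 0.137), with Tex15 at log2 −1.74.

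Genes that restrain apoptosis gave 5 higher, 1 lower and 16 not passing (adjusted p = 0.188), and Bcl2 rose from 176 ± 12.9 to 996 ± 59 (log2 2.40, adjusted p = 2.07e-05). Genes that promote it gave 6, 4 and 26 (adjusted p = 0.194). Dapk1 (log2 2.30) and the death ligand gene Tnfsf10 (83.3 ± 8.07 to 666 ± 208, log2 2.74) rose.

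Sex-linked transcripts separated the leukaemia groups. Wild-type leukaemias carried Xist at 4193 ± 543 and Eif2s3y at 7.31 ± 0.29, and knockout leukaemias Xist at 36.5 ± 4.36 and Eif2s3y at 519 ± 51.5 (log2 −6.32 and 4.52). The Y-linked Kdm5d (log2 3.17) and Uty (log2 1.54) were higher in the knockout leukaemias. Both thymocyte groups had low Xist (35.4 ± 9.07 and 39.7 ± 3.14) and Eif2s3y at 395 ± 167 and 262 ± 111. Genes of the X and Y chromosomes made up 3.13% of the 2493 calls and 3.06% of the genes tested.

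The arrays fell into 2 sets by the added poly-A control transcripts: dap gave 752 to 3524 on wild-type leukaemias 1 and 2, knockout leukaemia 1 and wild-type thymocytes 1 and 2, and 4.25 to 6.26 on the other 7 arrays. The ratio of Gapdh 3' to 5' signal, which rises as RNA degrades, ran from 0.964 to 1.14 on the 5 arrays with signal and from 1.12 to 3.68 on the others. With this set as a block the leukaemia genotypes differed in 1551 higher and 1146 lower genes. Fits within a set leave 1 array in a group, assumed to vary like the other group, and so do not by themselves settle the part of the set. Their arrays are also among the 6 that gave the calls, so a kept direction is no separate evidence. Among arrays with signal (2 wild-type, 1 knockout) the counts were 1701 and 1485, and among arrays without it (1 and 2) limma called 0 genes, 2028 at an unadjusted p under 0.05, with all 2493 genes in the same direction as with 6 arrays and Mbd2 at log2 −3.34 (adjusted p = 0.0653). Of the 19 lists that passed, 17 passed with the block, T-lineage factors and mature T cell genes both being at an adjusted p of 0.0661. The arrays with signal alone kept 14, losing T-lineage factors, mature T cell, homing, neutrophil and erythroid genes, and those without kept 15, losing T-lineage factors, mature T cell, mitosis and NF-κB genes.

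Leaving out 1 leukaemia array at a time kept 13 of the 19 lists in every fit. Notch targets were at an adjusted p of 0.0583, 0.0502 and 0.0916 without knockout replicate 1, knockout replicate 2 or wild-type replicate 3, and PI3K and FOXO genes at 0.0674 without wild-type replicate 3. Homing genes were at 0.0627, 0.058 and 0.108 without knockout replicates 1 or 3 or wild-type replicate 3, and mature T cell genes at 0.0583, 0.0726, 0.0506 and 0.0738 without knockout replicates 1 or 3 or wild-type replicates 1 or 2. T-lineage factors passed only when wild-type replicate 2 was the array left out.

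**Figure D3:**
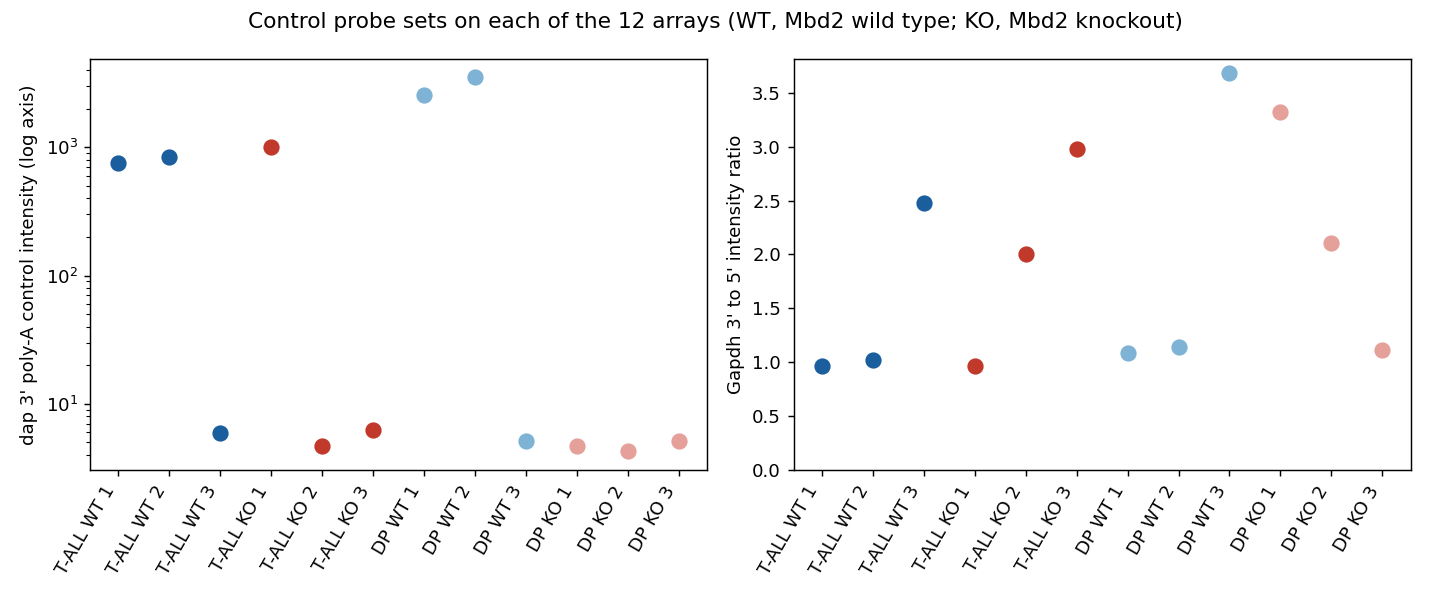
Intensity of the 3' probe set of the added dap poly-A control (left, log axis) and ratio of the Gapdh 3' to 5' control probe sets (right) on each of the 12 arrays.

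In CD4+CD8+ thymocytes the deletion lowered Mbd2 from 1136 ± 206 to 72.1 ± 10.7 (log2 −3.70, SE 0.16, n = 3 per group, adjusted p = 0.000718) and few other genes passed. The non-muscle myosin gene Myh10 rose from 62.5 ± 8.39 to 231 ± 8.02 (log2 1.66, SE 0.11, adjusted p = 0.00723) and the X-linked Fgf13 fell from 760 ± 9.11 to 218 ± 29.5 (log2 −1.73, SE 0.12, adjusted p = 0.00723). The kinase gene Pkn3 went from 100 ± 9.24 to 250 ± 13.5 (log2 1.20, SE 0.10, adjusted p = 0.0279) and the sorting nexin gene Snx10 from 49.4 ± 3.83 to 115 ± 5.66 (log2 1.00, SE 0.10, adjusted p = 0.0495). Notch1 (1596 ± 189 and 1557 ± 213), Cd4 (1630 ± 268 and 1502 ± 300), Cd8a (6184 ± 1241 and 6584 ± 1220) and Myc (85.1 ± 32.8 and 61.3 ± 27.7) did not pass (adjusted p 0.982 to 0.992).

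These 3 higher and 2 lower genes are all that limma called, with 722 at an unadjusted p under 0.05 and 1333 genes (8.64%, 10% by chance) without overlap between the groups. With the poly-A set as a block the genotype effect comes from wild-type replicate 3 alone against the 3 knockout arrays, which all lack signal, and the single array is assumed to vary like the others. In that fit only Mbd2 passed (log2 −3.59, adjusted p = 0.0156), and Myh10, Fgf13, Pkn3 and Snx10 were at adjusted p of 0.145, 0.145, 0.353 and 0.353. Leaving out single arrays also lost these calls: Myh10 was at 0.119 without knockout replicate 2, Fgf13 at 0.087 without wild-type replicate 1, Pkn3 at 0.307 and Snx10 at 0.269 without knockout replicates 2 and 1. The second Mbd2 probe set went from 288 ± 172 to 15.7 ± 5.24 (log2 −3.08, SE 0.44, adjusted p = 0.176). Filled in by smallest p, without passing, were Zfhx3 (log2 1.84, adjusted p = 0.0553), Igsf3 (log2 1.03, adjusted p = 0.0662), the prohormone convertase gene Pcsk1 (log2 −0.89, adjusted p = 0.0553), Tox3 (log2 −1.06, adjusted p = 0.0846) and Lpxn (log2 −1.05, adjusted p = 0.161).

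In leukaemias Myh10 moved the same way (log2 1.83, adjusted p = 0.000395), as did Pkn3 (log2 0.71, adjusted p = 0.0418). Snx10 did not pass there (log2 −0.10, adjusted p = 0.748). Fgf13 rose from 13.5 ± 2.15, below the background level of 35.3, to 71.4 ± 16.3 (log2 1.55, adjusted p = 0.000699).

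Thymocyte gene lists shifted by small amounts without a single member passing over all genes. Mitosis genes were higher (46 members, median log2 0.14, adjusted p = 1.44e-05, and 0.734 with an estimated correlation). S-phase genes (48 members, median 0.13, adjusted p = 0.000115, and 0.734 with an estimated correlation) and oxidative phosphorylation genes (41 members, median 0.17, adjusted p = 0.00043, and 0.398 with an estimated correlation) were higher too. Psrc1 (log2 0.42, adjusted p = 0.589), Gins2 (log2 0.46, adjusted p = 0.828) and Ndufb3 (log2 0.28, adjusted p = 0.982) are given as values of these lists. T-cell-receptor signalling genes were lower (29 members, median −0.20, adjusted p = 0.000274, and 0.734 with an estimated correlation). Prkcq, a kinase of this pathway, was at log2 −0.57 (adjusted p = 0.449), and over the list alone 0 members were higher and 1 lower. Interferon-stimulated genes were lower (41 members, median −0.18, adjusted p = 0.00043, and 0.819 with an estimated correlation), with Ifi47 at 1082 ± 280 and 453 ± 163 (log2 −1.25, adjusted p = 0.639). MHC class II genes were lower (10 members, median −0.28, adjusted p = 0.00133, and 0.734 with an estimated correlation), with H2-DMa at log2 −0.32 (adjusted p = 0.982). Monocyte and macrophage genes moved the same way without passing (22 members, median −0.10, adjusted p = 0.131, and 0.853 with an estimated correlation). Among them Lyz1 was at 161 ± 139 and 56.8 ± 41.9 (log2 −1.15, adjusted p = 0.982), with 321 on wild-type replicate 1, and C1qa was at log2 −0.59, but Csf1r at 0.04. Homing and adhesion genes were lower (27 members, median −0.12, adjusted p = 0.00393, and 0.398 with an estimated correlation), with Icam1 at log2 −0.66 (adjusted p = 0.529) and 0 and 2 members over the list alone.

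With the poly-A set as a block, again wild-type replicate 3 alone against 3 knockout arrays, the higher thymocyte lists passed (mitosis and S phase at 1.59e-07, oxidative phosphorylation at 0.0238). The lower lists did not pass with the block: T-cell-receptor signalling 0.416, interferon 0.911, homing 0.38 and MHC class II 0.782, the first 2 with the opposite sign. Leaving out knockout replicate 3 put mitosis at 0.378, S phase at 0.289, oxidative phosphorylation at 0.0566, homing at 0.0907 and MHC class II at 0.153. The interferon list was at 0.939 without wild-type replicate 1, and S phase at 0.142 without wild-type replicate 3, so that T-cell-receptor signalling alone passed in every fit with 1 array left out.

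Wild-type leukaemias carried high Mycn, which went from 68.9 ± 12.1 in wild-type thymocytes to 9456 ± 754 (log2 6.81, SE 0.14, n = 3 per group, adjusted p = 2.06e-06). Myc was also higher, 85.1 ± 32.8 against 701 ± 325 (log2 2.75, SE 0.43, adjusted p = 0.00253). The recombinase gene Rag1, active in CD4+CD8+ thymocytes, fell from 11101 ± 1928 to 39.4 ± 4.86 (log2 −7.64, SE 0.15, adjusted p = 2.06e-06) and Rag2 from 549 ± 110 to 10.1 ± 1.64 (log2 −4.42). Notch1 itself did not pass (1596 ± 189 and 1457 ± 140, adjusted p = 0.53), but its targets Dtx1 (169 ± 60.2 to 2911 ± 299, log2 4.03) and Nrarp (77.9 ± 3.04 to 640 ± 102, log2 2.79) were higher. Cd4 fell by log2 2.51 and Cd8a by log2 1.17, and Mbd2 did not pass (log2 −0.46, adjusted p = 0.0715).

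Wild-type leukaemias and thymocytes differed in 3031 higher and 2197 lower genes, 1357 and 1011 of them at least 2-fold. With the poly-A set as a block the counts were 3870 and 2790, and among arrays with signal (2 and 2) 3316 and 2401. These groups also differ in the sex-linked Xist (4193 ± 543 against 35.4 ± 9.07) and Eif2s3y (7.31 ± 0.29 against 395 ± 167). The leukaemias are marrow cells and the thymocytes thymus cells. Sex and tissue therefore cannot be told from leukaemia in this comparison. Further high genes were the metallothionein gene Mt1 (13.9 ± 5.39 to 2960 ± 379, log2 6.64), Xist (log2 6.36), Trnp1 (log2 4.94), Clvs1 (log2 4.90), Plac8 (log2 4.64), the asparagine synthetase gene Asns (log2 4.63), Cenpv (log2 4.40), Ahnak (log2 4.28) and Bst1 (log2 4.24). Besides Rag1, the largest losses were Selenop (log2 −5.89), Slc15a2 (log2 −5.59), Lsp1 (log2 −5.54), Nhsl1 (log2 −5.47), the semaphorin receptor gene Plxnd1 (2803 ± 334 to 59.8 ± 13.7, log2 −5.23), F13a1 (log2 −4.85), Ifi209 (log2 −4.79), Fgf13 (log2 −4.72) and Glcci1 (log2 −4.57).

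All 40 ribosome biogenesis genes were higher in wild-type leukaemias (list adjusted p = 2.29e-18, and 0.152 with an estimated correlation). Srm went from 199 ± 33.8 to 2044 ± 108 (log2 3.27), with the pyrimidine synthesis gene Cad at log2 3.07 and Mybbp1a at log2 2.34. S-phase genes followed (adjusted p = 6.96e-12, and 0.23 with an estimated correlation), with 41 higher, 0 lower and 7 not passing (42 and 0 over the list alone). Ung was at log2 2.00, Pold2 at 1.87 and Pole at 1.61. Mitosis genes were higher (adjusted p = 0.000822, and 0.389 with an estimated correlation), with 16 higher, 1 lower and 29 not passing (24 and 1 over the list alone) and Bub1b at log2 0.98.

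Oxidative phosphorylation genes were higher in wild-type leukaemias (adjusted p = 1.05e-07, and 0.152 with an estimated correlation), with 29 higher, 0 lower and 12 not passing (34 and 0 over the list alone) and Sdhb at log2 1.05. Cholesterol synthesis genes were higher (adjusted p = 1.98e-05, and 0.152 with an estimated correlation), with 13 higher, 0 lower and 7 not passing (18 and 0 over the list alone) and Cyp51 at log2 1.85. Glycolysis genes were higher (adjusted p = 0.000628, and 0.3 with an estimated correlation), with 14 higher, 2 lower and 7 not passing (16 and 2 over the list alone) and Aldoa at log2 2.49. The amino acid response and unfolded protein list was higher (adjusted p = 0.00992, and 0.275 with an estimated correlation), with 14 higher, 5 lower and 11 not passing (17 and 6 over the list alone). Asns and the mitochondrial serine enzyme gene Shmt2 (log2 3.10) led it.

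Genes of CD4+CD8+ thymocytes were lower, 22 members against 0 higher and 4 not passing (0 and 22 over the list alone), with Ets2 at log2 −3.65. The list had an adjusted p of 1.29e-14, and 0.152 with an estimated correlation. T-cell-receptor signalling genes were lower (adjusted p = 8.16e-11, and 0.255 with an estimated correlation), at 1 higher, 23 lower and 5 not passing (1 and 24 over the list alone). The kinase gene Fyn (log2 −1.49), Rasgrp1 (log2 −1.46) and Themis (log2 −2.04) were among those that fell. Interferon-stimulated genes were lower (adjusted p = 0.000568, and 0.588 with an estimated correlation), at 2 higher, 13 lower and 26 not passing (2 and 13 over the list alone). Gbp2 was at log2 −2.70 and Igtp at log2 −1.73. PI3K and FOXO genes were lower (adjusted p = 0.00109, and 0.152 with an estimated correlation), at 2, 13 and 11 (3 and 14 over the list alone), with Ccng2 at log2 −2.06. NF-κB targets were lower (adjusted p = 0.0131, and 0.23 with an estimated correlation), at 3, 9 and 11 (3 and 9 over the list alone), with Ltb at log2 −3.40.

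Erythroid and neutrophil genes were higher in wild-type leukaemias than in thymocytes, at low intensities. The erythroid list had 12 higher, 0 lower and 9 not passing, or 15 and 0 over the list alone (adjusted p = 0.000731, and 0.349 with an estimated correlation), with Epor at 110 ± 15.6 (log2 1.14). Neutrophil genes had 10 higher, 0 lower and 7 not passing, or 10 and 0 over the list alone (adjusted p = 0.00303, and 0.294 with an estimated correlation), with Ngp at 255 ± 37.7 (log2 2.12).

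The remaining lists that passed lay near the threshold. T-lineage factors gave 3 higher, 7 lower and 12 not passing (adjusted p = 0.0328, and 0.242 with an estimated correlation), with Bcl11b (log2 −1.58) lower and Runx3 (log2 2.25) higher. B cell genes gave 1, 5 and 13 (adjusted p = 0.0355, and 0.242 with an estimated correlation), with Pou2af1 (log2 3.87) higher and Cd79b (log2 −2.13) lower. Genes restraining apoptosis gave 4, 9 and 9 (adjusted p = 0.0445, and 0.358 with an estimated correlation), with Bcl2l1 (log2 −2.39) lower. Notch targets gave 9 higher, 3 lower and 8 not passing (adjusted p = 0.0478, and 0.358 with an estimated correlation). The genes linked to MBD2 gave 4, 0 and 6 (adjusted p = 0.0445, and 0.255 with an estimated correlation), with Xist (log2 6.36), which marks the sex of the mice here, and Cela1 (log2 2.59) among the higher ones. Without Xist this list did not pass (adjusted p = 0.161, and 0.358 with an estimated correlation). Without wild-type thymocyte replicate 2 these 5 lists were at adjusted p of 0.0931, 0.0526, 0.0615, 0.0615 and 0.0615.

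The other 14 lists passed with any array left out. With the poly-A set as a block Notch targets were at 0.0567 and the genes linked to MBD2 at 0.0673, while the other 17 lists passed, and the arrays with signal alone kept all 19. With the replicate number as a block these 2 lists were at 0.0762 and 0.0812. Cell cycle inhibitors (0.0774 without it), immediate early genes (0.0631) and homing genes (0.0554) then passed as lower, at 0.0428, 0.0446 and 0.0446.

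Knockout leukaemias stood apart from knockout thymocytes through Cpa3 (23.2 ± 4.41 to 7622 ± 622, log2 7.61, SE 0.12, n = 3 per group, adjusted p = 4.22e-07) and the T-cell-receptor gamma segment gene Trgv1 (47.7 ± 4.43 to 6610 ± 868, log2 6.69, SE 0.13, adjusted p = 5.57e-07). Mycn was high here too (81.9 ± 18.1 to 5610 ± 768, log2 5.85, SE 0.17, adjusted p = 2.79e-06), as was Myc (61.3 ± 27.7 to 589 ± 326, log2 2.87). Rag1 fell from 11113 ± 1731 to 18.5 ± 7.61 (log2 −8.35, SE 0.20, adjusted p = 1.18e-06), Cd8b1 from 8268 ± 2780 to 62.3 ± 33.2 (log2 −6.74) and Cd4 from 1502 ± 300 to 92.7 ± 1.24 (log2 −3.79). Notch1 was higher than in thymocytes (log2 1.83, SE 0.20, adjusted p = 0.000495), and Mbd2 did not pass (log2 −0.33, adjusted p = 0.183).

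The counts were 2845 higher and 1694 lower genes, 1362 and 727 at least 2-fold. Only 1 of these 6 arrays, knockout leukaemia 1, carried the poly-A signal, and without it the counts were 2392 and 1442 and 10 of the 11 lists that passed did so again. Other large gains were Pdgfrb (log2 6.60), Cd93 (log2 6.34), Hhex (log2 6.14), Tgfb2 (log2 6.14), the basic helix-loop-helix gene Lyl1 (log2 5.98), Trnp1 (log2 5.96) and Gzmb (log2 5.90). Large losses were Ly6d (log2 −6.23), Ccr9 (log2 −6.03), Ctsl (log2 −5.40), Glcci1 (log2 −5.37), Cd8a (log2 −4.97), Dgkeos (log2 −4.91), Lsp1 (log2 −4.75) and Ssbp2 (log2 −4.61).

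Thymocyte identity genes were lower in knockout leukaemias as well (adjusted p = 1.72e-17, and 0.13 with an estimated correlation), with 0 higher, 22 lower and 4 not passing (0 and 23 over the list alone) and Slamf1 at log2 −3.23. Ribosome biogenesis genes were higher (adjusted p = 1.11e-15, and 0.253 with an estimated correlation), with 38 higher, 0 lower and 2 not passing (39 and 0 over the list alone) and Utp20 at log2 2.75. S-phase genes were higher (adjusted p = 0.00392, and 0.62 with an estimated correlation), with 18 higher, 2 lower and 28 not passing (19 and 2 over the list alone). Mcm3 (log2 1.04) and Ung (log2 1.40) rose and E2f8 (log2 −0.96) fell. Glycolysis genes were higher (adjusted p = 0.00278, and 0.321 with an estimated correlation), at 16, 2 and 5 (16 and 3 over the list alone), with Pgam1 at log2 2.07. The amino acid response list was higher (adjusted p = 0.00392, and 0.62 with an estimated correlation), at 16, 3 and 11 (18 and 5 over the list alone), with the leucine transporter gene Slc7a5 at log2 3.27.

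Interferon-stimulated genes were higher in knockout leukaemias than in their thymocytes (adjusted p = 0.00278, and 0.667 with an estimated correlation), with 17 higher, 3 lower and 21 not passing (20 and 3 over the list alone). Oas1a was at log2 1.62 and Oas3 at log2 1.47. Effector genes were higher (adjusted p = 0.00392, and 0.62 with an estimated correlation), at 11, 0 and 17 (11 and 0 over the list alone), with Il18r1 at log2 5.05. Notch targets were higher (adjusted p = 0.016, and 0.62 with an estimated correlation), at 11, 2 and 7 (11 and 2 over the list alone). Dtx1 was at log2 4.81 and Nrarp at log2 4.14, against Ptcra at log2 −3.34.

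T-cell-receptor signalling genes were lower (adjusted p = 0.00392, and 0.62 with an estimated correlation), at 4 higher, 14 lower and 11 not passing (4 and 14 over the list alone), with Cd2 at log2 −2.45. Cell cycle inhibitors were lower (adjusted p = 0.0186, and 0.537 with an estimated correlation), at 2, 8 and 6 (2 and 9 over the list alone), with the antiproliferative gene Btg2 at log2 −2.47. Megakaryocyte genes were higher (adjusted p = 0.0461, and 0.62 with an estimated correlation), at 4, 0 and 6 (4 and 0 over the list alone). This call was lost without knockout thymocyte replicate 3 (0.144) or knockout leukaemia replicates 1 (0.052) or 3 (0.0658).

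Oxidative phosphorylation genes (3 higher, 1 lower, 37 not passing, adjusted p = 0.736), cholesterol synthesis genes (4, 2 and 14, adjusted p = 0.462) and mitosis genes (3, 3 and 40, adjusted p = 0.735) did not pass in knockout leukaemias against their thymocytes. Across the genes tested, the leukaemia differences of the 2 genotypes, which share no arrays, correlated with a Pearson r of 0.618 (Spearman 0.609). They shared 1660 higher genes, where 559 would be shared by chance, and 1179 lower genes (241 by chance), while 209 genes passed in opposite directions. Tissue goes with leukaemia in both genotypes, and the sex-linked Xist goes with it only in the wild type. Shared and separate genes therefore cannot be ascribed to leukaemia alone.

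**Figure D4:**
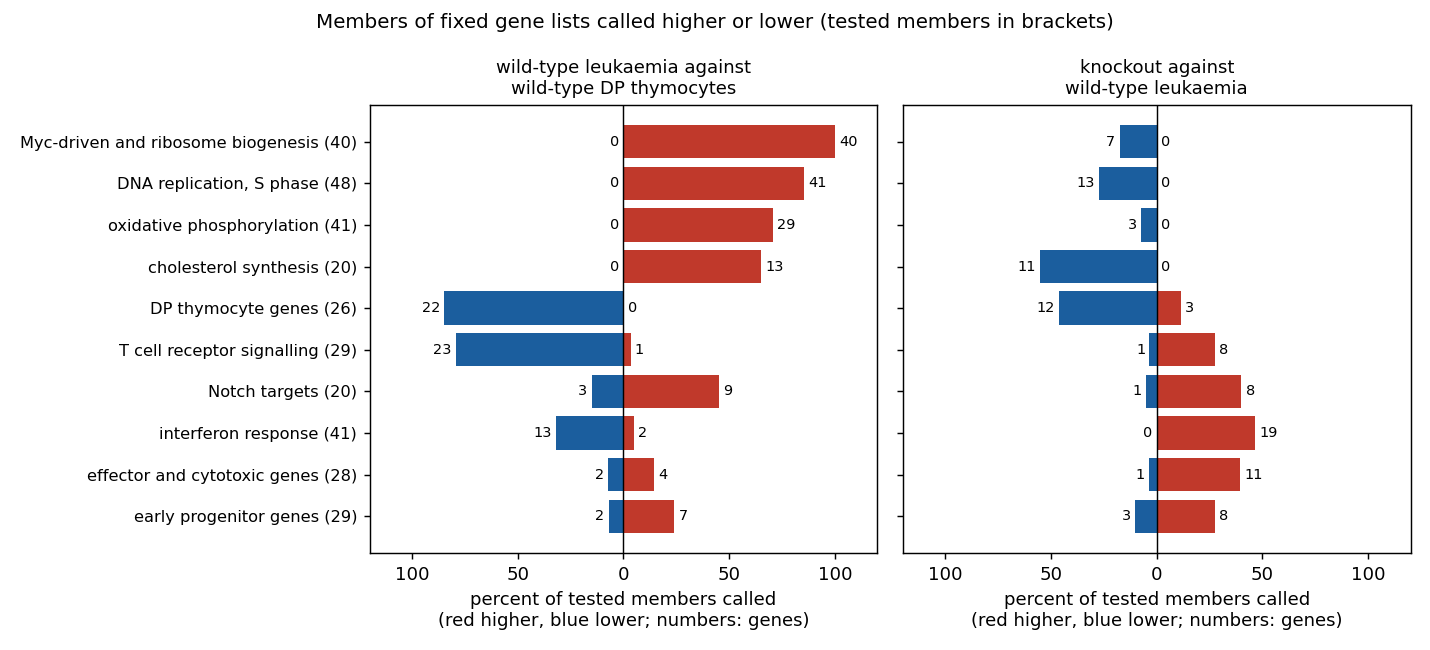
Percent of the tested members of 10 gene lists called higher (red) and lower (blue) in wild-type leukaemias against wild-type thymocytes (left) and in knockout against wild-type leukaemias (right), 3 arrays per group.

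The difference between genotypes, which in the leukaemias goes with a difference in sex-linked transcripts, was not the same in leukaemia and thymocytes for 1943 genes, 1212 with a higher and 731 with a lower effect in leukaemia. Higher effects made up 62.4% of these, and 47.8% when arrays were centred on their 75th percentile, which moved the median difference of all genes from −0.05 to −0.18. Cpa3, Cd93, Tgfb2, Pdgfrb and Hhex had the largest positive differences (log2 7.65, 7.00, 6.19, 6.10 and 6.08), and Xist, a marker of sex, Cttn, Ptcra, Cd8b1 and Nrp1 the largest negative ones (log2 −6.45, −6.08, −5.35, −5.34 and −4.60). The difference in the fall of Mbd2 between the cell types did not pass (difference 0.12, SE 0.24, adjusted p = 0.818). With the poly-A set as a block 2425 genes differed, and among the 7 arrays without signal, which hold 1 wild-type array per cell type, 612.

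Interferon-stimulated genes had a higher effect in leukaemia (list adjusted p = 1.26e-09, and 0.281 with an estimated correlation), with 18 higher, 0 lower and 23 not passing. Effector genes (10, 0 and 18, adjusted p = 6.75e-05, and 0.237 with an estimated correlation) and T-cell-receptor signalling genes (8, 1 and 20, adjusted p = 1e-04, and 0.312 with an estimated correlation) did too. S-phase genes (0, 9 and 39, adjusted p = 1.14e-08, and 0.237 with an estimated correlation) and oxidative phosphorylation genes (0, 3 and 38, adjusted p = 3.99e-07, and 0.237 with an estimated correlation) had a lower effect in leukaemia. So did thymocyte identity genes (2, 9 and 15, adjusted p = 0.00826, and 0.318 with an estimated correlation). Across all genes tested the genotype effects of the 2 cell types had a Pearson r of −0.06 (Spearman −0.07), and 268 of 400 swaps of arrays between genotypes gave a correlation as large.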

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

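The tests of the poly-A set and of RNA integrity for the leukaemia genes, of 1 clone per genotype, of monocytes in the sort, and of the poly-A set for the thymocyte lists were chosen only after the results were seen. The poly-A set and the Gapdh ratio were taken up only after the data were seen, which holds for every test that uses them.

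Leukaemias of the 2 genotypes differed in 2493 genes where thymocytes differed in 5. Labelling batch or RNA integrity would lose most calls once adjusted for, but 2278 of 2493 kept call and direction with the poly-A set as a block and 2403 with the Gapdh ratio as a covariate. The Gapdh ratio divides the leukaemia arrays as the poly-A set does, so these are not separate checks. The wild-type leukaemias look female and the knockout ones male, yet only 3.13% of the calls lie on the X and Y chromosomes. Few calls are therefore sex-linked genes themselves. This share says nothing about effects of sex on genes of other chromosomes, which cannot be told from genotype here. The 3 leukaemias of a genotype may derive from 1 clone. Genes ranging over 4-fold between replicates were 4 in leukaemias and 28 in thymocytes of the wild type (ratio 0.143). In the knockout they were 21 and 4 (5.25), so the pooled ratio of 0.781 leaves this open. Median log2 SDs were similar, 0.154 and 0.165 in wild-type and knockout leukaemias and 0.156 and 0.151 in the thymocytes, and do not settle it. With 1 clone each, the difference between clones, sex included, could not be told from the effect of the deletion, and leukaemias from more founder mice of both sexes per genotype would separate them.

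In thymocytes 7 lists shifted in the knockout without a member passing, and 0 lists passed with an estimated correlation (lowest adjusted p = 0.398). In the test made for RNA integrity, 7 of 7 lists kept call and direction with the Gapdh ratio as a covariate. This cannot exclude RNA integrity, because 7 of 10 splits of these 6 arrays, the real one among them, gave as many lists. Labelling batch cannot be told apart from genotype here, because the arrays without signal hold all 3 knockout samples but 1 wild-type sample, replicate 3, which has the highest Gapdh ratio of the 12 arrays (3.68). Against this array 3 of 3 higher lists and 0 of 4 lower lists kept their call, which decides neither. The higher lists also rest on knockout replicate 3, without which mitosis had an adjusted p of 0.378, so proliferation of that sample stays open, as do fewer macrophages in the knockout sorts for the lower MHC class II and interferon lists (macrophage list median log2 −0.10, adjusted p = 0.131).

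Interferon-stimulated genes were higher in knockout leukaemias (adjusted p = 1.71e-09, and 0.332 with an estimated correlation). Monocytes, macrophages or dendritic cells in the sort could carry such transcripts, but the median log2 difference of their list was −0.0888, with Csf1r at 78.3 and 68.8 and Lyz2 at 55.4 and 31.3 in wild-type and knockout leukaemias, although Cd163 rose from 8.1 to 69 (log2 1.73, adjusted p = 0.00879). RNA integrity and labelling batch are unlikely sources, as 18 of 19 called members kept their call with the Gapdh ratio as a covariate and 18 of 19 with the poly-A set as a block. These are not separate checks. On the leukaemia arrays the ratio was 0.964 to 1.02 with poly-A signal and 2.00 to 2.98 without it. A response within the leukaemia cells or a property of a clone stays open, and measuring interferon in the marrow would help to decide.

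The 6 arrays of a comparison can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. For leukaemia genotype 1 of 10 splits, the real one, gave as many genes (2493, highest other 0) and 1 of 10 as many lists (19, highest other 10). For wild-type leukaemias against thymocytes the same held with 1 of 10 for genes (5228, highest other 0) and 1 of 10 for lists (19, highest other 16). For knockout leukaemias it was 1 of 10 for genes (4539, highest other 0) and 3 of 10 for lists (11, highest other 11). For thymocyte genotype 2 of 10 splits gave as many genes (5, highest other 777) and 7 of 10 as many lists (7, highest other 10). The split with 777 genes puts wild-type replicates 1 and 2 with knockout replicate 3, the 3 arrays with the lowest Gapdh 3' to 5' ratio, which points to a structure of the samples other than genotype. With that ratio as a covariate 7 higher and 3 lower genes passed. For the difference of the genotype effects 2 of 100 relabellings gave as many genes (1943, highest other 2937). The 11 relabellings that kept the leukaemia genotypes reached up to 2937 and all others at most 1, so the count rests on the leukaemia arrays.

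The genotype effect differed between leukaemia and thymocytes for 1943 genes and 20 lists, of which 0 passed with an estimated correlation (lowest adjusted p = 0.222). By log2 difference of the effects the genes with higher values in leukaemia were Cpa3 7.65, Cd93 7.00, Tgfb2 6.19, Pdgfrb 6.10, Hhex 6.08, Angpt1 6.05, Gzmb 5.97, F2r 5.73, Ifitm2 5.41, Lmcd1 5.30 and Notch1 1.96. Of the sex-linked genes Eif2s3y was at 5.05, Kdm5d at 3.38, Uty at 1.98 and Xist at −6.45. The genes with lower values in leukaemia were Cttn −6.08, Ptcra −5.35, Cd8b1 −5.34, Nrp1 −4.60, Ccr9 −4.00, Dsp −3.82, Cd8a −3.80, Slc36a4 −3.74, Ctsl −3.47, Slc30a4 −3.29 and Cd4 −1.27. Some genes named for thymocytes differed as well, Fgf13 by 3.29, Tox3 by 1.09, Pcsk1 by 1.01, Lpxn by 0.90, Snx10 by −1.09 and Igsf3 by −3.05. All these had an adjusted p between 1.02e-10 and 0.0315. The thymocyte calls Myh10 (difference 0.16, adjusted p = 0.691) and Pkn3 (difference −0.49, adjusted p = 0.192) did not pass. Tox3 and Pcsk1 lay below the background level of 35.3 in both leukaemia groups, so their differences only restate the thymocyte values.

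The added dap poly-A control gave at least 752 on 5 arrays and at most 6.26 on the other 7, which marks a difference in sample preparation that the labels do not mention.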

How the results depend on the processing

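The poly-A set, the Gapdh covariate, and the results without X and Y genes or without Xist in the MBD2 list were chosen only after the results were seen, and the other settings before. Over all named genes 9612 of 10146 results under another setting kept their side, 430 lost a call, 76 gained it and 28 changed sign without passing. Of the 430 lost calls, 151 came from the arrays without poly-A signal, which leave 3 leukaemias. The cause of the differences described here was not tested unless stated.

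All list calls depend on how camera was set. With a correlation estimated per list 0 lists passed for leukaemia genotype, 0 for thymocyte genotype and 0 for the difference of effects. For leukaemias against thymocytes 0 passed in the wild type and 0 in the knockout. The size of the correlation alone does not account for this. In thymocytes, oxidative phosphorylation genes had an estimated correlation of 0.00994, near the preset 0.01. Their adjusted p still went from 0.00043 to 0.398. For leukaemia genotype, megakaryocyte genes had an estimated correlation of −0.0595, below the preset, and went from 0.00236 to 0.262. Asking for a 2-fold difference lowers counts by construction, to 802 higher and 387 lower for leukaemia genotype, 1357 and 1011 for wild-type leukaemias, 1362 and 727 for knockout leukaemias and 1266 for the difference of effects.

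For leukaemia genotype the lower genes numbered 1656 with 75th percentile centring and 1936 with the replicate block. The arrays without poly-A signal gave 0 higher and 0 lower genes, and Mbd2 at log2 −3.34 (adjusted p = 0.0653). Without wild-type replicate 1 lower genes numbered 607, and without replicate 2 there were 877 higher and 535 lower. Over all left-out arrays higher genes reached 1432 and lower genes 1057, and Mbd2 lay between log2 −3.70 and −3.44 and lists between 14 and 19. Myc, which did not pass, changed sign to 0.55 without signal and 0.042 with the Gapdh ratio, and ran from −0.75 without wild-type replicate 3 to 0.20 without knockout replicate 3.

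For thymocyte genotype higher and lower genes were 6 and 5 with 75th percentile centring, 6 and 5 with trend and robust, 11 and 6 with array weights and 8 and 5 with all 12 arrays in the fit. Lower genes were 4 with an added constant of 1, and 1 without X and Y genes because Fgf13 is X-linked. Higher genes were 7 with the Gapdh ratio. The poly-A set as a block gave 0 and 1 genes and 4 lists, and the arrays without signal likewise 0 and 1 genes and 4 lists, both from wild-type replicate 3 alone against the 3 knockout arrays. Lists numbered 12 with 75th percentile centring, 13 with the mean of the probe sets and 12 with a constant of 1. Leaving out wild-type replicates 1 or 2 gave 0 or 1 higher and 1 lower gene, and leaving out knockout replicates 1, 2 or 3 gave 0 higher and 1, 2 and 1 lower. Lists numbered 2 without knockout replicate 3 and 10 without wild-type replicate 1.

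Equal replicate numbers did not pair in thymocytes (r of −0.52, 0.14 and −0.49) nor between knockout leukaemias and thymocytes (−0.39, 0.09 and −0.43), so this block fits a term without a shared source there. With it limma called 0 higher and 0 lower genes in thymocytes (419 at an unadjusted p under 0.05), with Mbd2 unchanged at log2 −3.70 (adjusted p = 0.07), and 3513 genes for knockout leukaemias. In the comparisons where numbers do pair it changed no call of a gene or list in the text other than those given.

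Thymocyte genes that did not pass changed sign under some settings. Notch1 was at 0.024 with 75th percentile centring and 0.043 with the mean of the probe sets, and with an array left out it ran from −0.14 (wild-type replicate 2) to 0.070 (knockout replicate 1). Cd8a was at −0.17 with the mean of the probe sets, and ran from −0.073 (without wild-type replicate 3) to 0.25 (without knockout replicate 1). Cd4 was at 0.086 with the mean of the probe sets. With the poly-A set as a block or without signal Cd4 was at 0.13 and 0.13, Xist at −0.15 and −0.15, Eif2s3y at 0.24 and 0.24 and Myc at 0.21 and 0.21.

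For the difference of effects, array weights gave 2920 genes and the arrays without signal 612. Its value for Myc, which did not pass, changed sign to −0.024 with 75th percentile centring, −0.0068 with a constant of 64 and −0.18 with the poly-A set as a block. With an array left out it ran from −0.35 (wild-type leukaemia 3) to 0.60 (knockout leukaemia 3), and was negative in 5 fits. The correlation of effects was −0.045 with the poly-A set as a block and −0.11 with the Gapdh ratio, and ran from −0.12 without wild-type leukaemia 1 to −0.0060 without wild-type leukaemia 3.

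With single arrays left out, wild-type leukaemias against thymocytes gave 2333 to 2994 higher and 1568 to 2352 lower genes, and knockout leukaemias 2038 to 2861 and 1252 to 1622. In leukaemia against thymocytes, quantile normalization put Notch targets at an adjusted p of 0.0605, the genes linked to MBD2 at 0.054 and genes restraining apoptosis at 0.054 in the wild type. Centring on the 75th percentile put Notch targets at 0.053. Without Xist the genes linked to MBD2 were at 0.161 (0.358 with an estimated correlation) for wild-type and at 0.0472, now passing (0.62), for knockout leukaemias, and Notch targets at 0.0504 for the wild type. Levels under 35.3 cannot be told from background, which limits the size of differences for genes silent in a group.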

Other observations

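Of 9 tested segments of the T-cell-receptor loci, examined only after their values were seen, 3 differed by more than log2 4 between the leukaemia groups. The gamma segment Trgv4 was at 19.7 ± 2.02 in wild-type and 1768 ± 103 in knockout leukaemias (log2 5.64, SE 0.10, n = 3 per group, adjusted p = 1.1e-06), and Trgv1 at 180 ± 91.2 and 6610 ± 868 (log2 5.18, adjusted p = 0.000105). The beta segment Trbv13-2 was at 14.5 ± 1.59 and 739 ± 32.6 (log2 4.63, adjusted p = 1.39e-06), while thymocytes of both genotypes carried it at 436 ± 118 and 367 ± 80.7. Trav6-3 rose less (log2 1.39, adjusted p = 0.0234) and Trav13-5 fell slightly (log2 −0.40, adjusted p = 0.0356). Trbv1 (log2 −0.62, adjusted p = 0.222), Trav12n-1 (log2 −0.12), Trav12n-2 (log2 0.44, adjusted p = 0.0572) and Trav9d-3 did not pass. The probe set used for Trav9d-3 gave high and similar levels of 3591 ± 1182 and 3716 ± 823 (log2 0.08, adjusted p = 0.896). Other Trav9d-3 probe sets were high in both groups or low in both, as with 38.5 to 77.0 in wild-type and 45.3 to 53.5 in knockout leukaemias. Another Trbv1 probe set, not tested, was at 105 to 210 in wild-type and 48.5 to 58.5 in knockout leukaemias. A receptor segment far higher in all 3 samples of a genotype is what 1 clone per genotype would leave, but transcription of unrearranged segments could give the same values, and the test of the spread between replicates decided nothing (pooled ratio 0.781, wild type 0.143, knockout 5.25). Sequencing of the rearranged receptors would tell these apart.

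The receptor gene Il2rb rose in knockout leukaemias (log2 0.88, adjusted p = 0.00105), as did the granzyme gene Gzma (log2 2.10, adjusted p = 0.00206), both also listed for natural killer cells, and the B-lineage kinase gene Blk (47.9 ± 5.05 to 648 ± 185, log2 3.34). Among immediate early genes, whose list did not pass (6 higher, 1 lower, 22 not passing, adjusted p = 0.113), Dusp2 (log2 1.70), Dusp1 (log2 1.42) and Nr4a3 (log2 1.11) rose. The cell cycle inhibitors Cdkn1a (log2 0.99, adjusted p = 0.0182) and Cdkn2a (log2 0.69, adjusted p = 0.0374) rose and Gadd45b fell by log2 1.36 (adjusted p = 0.0262), but each of these calls was lost with some array left out.

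Of the tests in this part, those of a shared effect and of genes near Mbd2 were set out before their results were seen, and the clone ratio after. An effect of the deletion shared by all T-lineage cells would give the called leukaemia genes similar differences in thymocytes. Their correlation was −0.0659, within the range of swapped arrays (up to 0.244), so these genes as a set showed no shared effect. Sex, and possibly clone, goes with genotype in the leukaemias. Calls due to either could hide a shared effect, so the test cannot exclude one. Besides Mbd2, the thymocyte calls Myh10 and Pkn3 rose in both cell types. Fgf13 fell in thymocytes and rose in leukaemias, where its wild-type level lay below the background of 35.3. It is X-linked, so sex cannot be told from genotype for its rise. Snx10 did not pass in leukaemias. An effect that needs active Notch1 could also exist and would not be seen in thymocytes.

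Flanking DNA of the stem cell strain used for targeting may change genes near Mbd2. In thymocytes 3 of the 40 nearest tested genes (7.5%) had an unadjusted p under 0.05 against 4.67% of the others (one-sided Fisher's exact p = 0.287), and in leukaemias 16 of 40 (40%) against 28.9% (one-sided Fisher's exact p = 0.0884), so these data do not settle it. Genotyping of strain markers near Mbd2 would.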
